A study of Pseudotsuga menziesii with 10 samples.

How the data were processed

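RNA of 8 pools of Douglas-fir megagametophytes, of cone scales and of cone bracts was sequenced as polyA RNA with paired-end reads that do not keep the strand, per the labels' protocols. The submitters' processing notes name FastQC 0.10, Trim Galore 0.2, Bowtie 1.0.1, RSEM 1.2.12, bedtools 2.17 and R 3.1.0, without saying what each was used for. The contigs carry the accession numbers of a transcriptome assembly, per the file headers. The authors deposited 1 table of 54889 contigs and 10 libraries on a log scale that was read here as log2(FPKM + 1). The base and offset of the logarithm are not given in the sources used here. The values lie between 0.01 and 12.28. Undoing log2(FPKM + 1) gives sums of 466481 to 561810 FPKM per library, and undoing a natural logarithm would give 3645598 to 5440731. Every FPKM level and fold in the text rests on this reading.

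Each contig reached a value of at least 1.01 in 1 library or more, so no contig low in all 10 libraries is in the table. The 149 values at or above 10 fell on 39 distinct levels of 229 possible at the rounding of the table. The number of contigs at 10 FPKM or more was nearly equal in all libraries. Both features are what a common distribution imposed on a larger set of contigs would leave. Contigs at 1 FPKM or more, however, ranged from 22662 to 39644 per library, and the highest values from 10.6 to 12.28. A common distribution would have made these equal too, unless contigs were also left out on other grounds. No source names a step that imposes a common distribution, and whether it was taken stays open. Such a step would remove differences between libraries in overall level. Reads and depth per library are unknown, since rounded log values with shared levels do not return read counts, and no counting error is given. Related contigs of 1 gene could share reads in ways the table does not show. No columns had identical values, and the highest correlation between libraries was 0.959.

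Libraries were assigned to groups by pollination state, date and tissue from the labels. No group had a second library among those used here, and all libraries came from a single clone and year. Therefore p-values measure only departures from a straight line over dates, variation of the pollination difference between dates, or variation among libraries within tissue groups. Pools average over many seeds and show nothing about variation between trees.

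Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on log2(FPKM + 1), the pseudocount being 1 FPKM. A fold on this scale understates the change of low contigs. Contigs with a mean of 1 FPKM or more over the libraries of a test were kept, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The date test fitted 1 slope per day with pollination state as a term and 5 residual degrees of freedom, and changes are given over 26 days. The pollination test had date as a block and 3 residual degrees of freedom. The interaction of day and pollination, without a block for date, left 4, and the test of 8 megagametophyte libraries against scales and bracts left 8. Single pairs of libraries were described by contigs 2-fold or more apart with the higher value at 10 FPKM or more. Other summaries used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.

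The tests, the filter, the naming rule and most alternatives were set before the data were examined. The naming rule took the contigs with the largest fitted difference in each direction among those that passed, or the smallest p where none passed, and required an annotated name. The table pairs no names with the contigs, so that requirement was dropped and at most 2 contigs per direction are named in each comparison. For the same reason 26 gene lists fixed by annotation words, and their set tests, were not used here. The design had assumed FPKM values, and the deposited log values were converted to that scale.

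Models of the same form as the limma tests were fitted to data simulated from the libraries' own means and spread. The simulation started from filtered log2 values, so the filter and the conversion of values were not part of it. In each simulation 50 contigs were changed at each of 2, 4, 8 and 32-fold. The date test recovered 0%, 26%, 60% and 84% of them, and the pollination test 24%, 62%, 74% and 92%. The interaction recovered 0%, 0%, 0% and 6% (0% at every size with date as a block), and the tissue test 2%, 44%, 56% and 90%. Few contigs were changed in each simulation, and noise was drawn independently for each library. These shares therefore do not give the recovery in the libraries themselves, where many contigs changed together. In them 8853 contigs passed for date, 7912 at 2-fold or more, so smaller changes were called too. Alternatives covered the pseudocount, the filter, 3 rescalings, the eBayes settings, the threshold, the form of the date term, the date block and the omission of libraries or dates. Rescaling moved the median difference between 6 July and 10 June from 0.06 log2 units as deposited to 0.17 under quantile normalization and 0.25 when each library was rescaled to a common sum. It moved the median tissue difference from 0.24 to 0.43 under quantile normalization. Changes are reported on the deposited scale.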

Results

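Transcript levels were measured by RNA sequencing in seeds of Douglas-fir (Pseudotsuga menziesii) before and after fertilization. The megagametophyte, the haploid female gametophyte that surrounds and feeds the conifer embryo, was dissected from cones of a single clone on 10, 22 and 30 June and 6 July 2011. Cones had been bagged and either given a pollen mix or left without pollen. Per the labels, these dates coincided with formation of the corrosion cavity (the space into which the embryo grows), fertilization, embryogenesis, and early abortion in ovules without pollen. Each of the 8 combinations of date and pollination state is represented by 1 library made from a large pool of megagametophytes. Cone scales and cone bracts, diploid sporophyte tissue collected from the same clone on 26 May, gave 1 library each. No group had a second library, so every test below takes its error from other dates or tissues.

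The table holds 54889 assembled transcripts (contigs) in 10 libraries. Contigs at 10 FPKM (fragments scaled to contig length and library size) or more numbered 8468 to 8815 per library. Contigs at 1 FPKM or more ranged from 22662 in the pollinated megagametophytes of 22 June to 39644 in the bracts. The files do not pair the contig identifiers with gene names, so contigs are named by identifier and no gene families are described. The number of reads per library is unknown, and no counting intervals are given.

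Megagametophyte libraries of the same date were the most alike. In 8 of 8 cases the library with the highest correlation was the one of the same date and the other pollination state. Same-date correlations across contigs were 0.943 to 0.959. Neighbouring dates of the same pollination state correlated at 0.841 to 0.931. The first and last dates correlated at 0.718 in pollinated and 0.684 in unpollinated megagametophytes. Scales and bracts correlated at 0.868. The first principal component of the 8 libraries held 64.8% of the variance and ordered them by date, and the second held 13.2%. Contigs are not independent replicates, so these correlations carry no p-value.

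**Figure D1:**
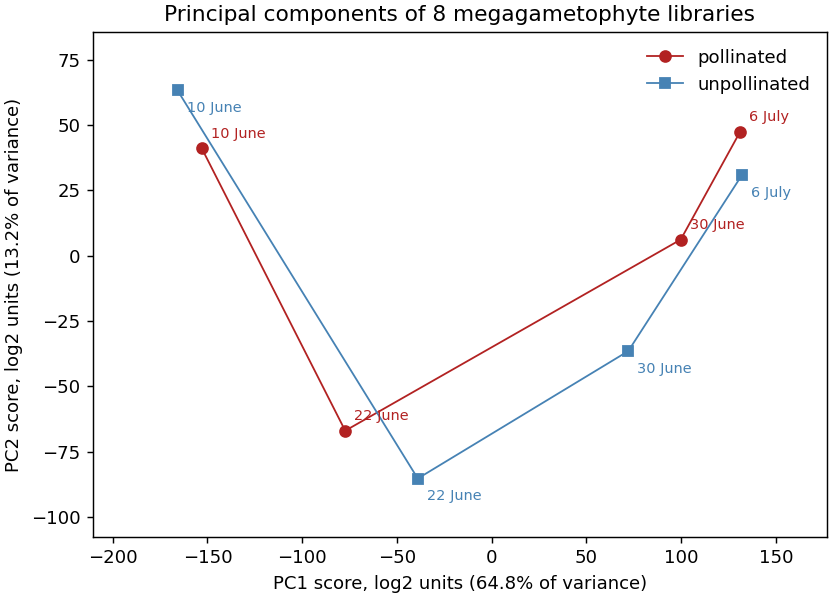
Positions of the 8 megagametophyte libraries on the first (64.8% of variance) and second (13.2%) principal components of log2(FPKM + 1), 1 point per library. Along the first component the libraries run from 10 June at the left to 6 July at the right.

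The question of how the megagametophyte transcriptome changes through late development was addressed over the 4 dates. Transcripts among the most abundant on 10 June were nearly absent on 6 July. GAZW02012967 stood at 1697 FPKM in pollinated and 2895 FPKM in unpollinated megagametophytes on 10 June and at 0.283 and 0.729 FPKM on 6 July, and GAZW02022487 went from 2451 and 4972 FPKM to 0.729 and 1.36 FPKM. Among the contigs that rose, GAZW02015617 went from 0.0425 and 0.0718 FPKM to 791.4 and 934.8 FPKM, and GAZW02100832 from 2.01 and 0.0425 FPKM to 796.9 and 848.2 FPKM. In limma, 8853 of 27065 contigs changed with date, 4402 upward and 4451 downward. This balance turned with the scale and the filter, to 5313 and 4400 under quantile normalization and 3399 and 2632 at a mean of 5 FPKM or more. A change of 16-fold or more over the 26 days was fitted for 225 contigs that rose and 988 that fell.

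The fitted changes over 26 days, on the log2(FPKM + 1) scale, were -11.81 ± 1.58 (SE) for GAZW02012967 and -11.59 ± 1.74 for GAZW02022487, with limma adjusted p of 0.00180 and 0.00269. GAZW02015617 changed by 9.64 ± 1.92 and GAZW02100832 by 9.30 ± 1.01, with limma adjusted p of 0.00770 and 0.00113. All 4 moved the same way in both pollination states. At an unadjusted p under 0.05 there were 11796 contigs. The test treats the 2 libraries of a date as independent, and wrong orders of the dates gave up to 6577 contigs, so the count has no fair chance value. On the mean of the 2 libraries of each date, a fit chosen after the data were examined, limma gave 2423 contigs (828 up, 1595 down), GAZW02015617 not among them (adjusted p 0.0534). The count fell to 2652 without both libraries of 10 June, to 5623 without both of 6 July, to 4541 without the pollinated and to 4675 without the unpollinated library of 10 June. The 4 pollinated libraries alone gave 0 contigs in limma (6889 at an unadjusted p under 0.05) and the 4 unpollinated ones 1827, and no contig named here passed in the pollinated libraries alone (differences of -11.86 to 10.36 log2 units, adjusted p 0.0675 to 0.0750). Without both libraries of 10 June the fitted change was wider, at 17.65 log2 units for GAZW02015617 and -18.29 for GAZW02022487. GAZW02015617 changed by 9.64 log2 units in the full fit. Without 6 July its slope, also stretched to 26 days, gave 6.48, and the unpollinated libraries alone gave 8.92. GAZW02015617 lost its call in both (limma adjusted p 0.111 and 0.0981).

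Sets defined after the data were examined describe this turnover. There were 264 contigs at 100 FPKM or more in both libraries of 10 June and under 1 FPKM in both of 6 July. They made up 16.2% of all FPKM in each library of 10 June. Their median level in pollinated megagametophytes was 250.6 FPKM on 10 June, 147.1 on 22 June, 0.390 on 30 June and 0.0570 on 6 July. In unpollinated megagametophytes it was 242.0, 78.9, 2.35 and 0.257 FPKM. Of the 264 contigs, 194 were under 1 FPKM in both scales and bracts. The opposite set, under 1 FPKM in both libraries of 10 June and at 100 FPKM or more in both of 6 July, held 12 contigs.

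With date as a 4-level factor, limma gave 5147 contigs between 10 and 22 June (2026 up, 3121 down), 2415 between 22 and 30 June (981 up, 1434 down) and 472 between 30 June and 6 July (346 up, 126 down). These intervals of 12, 8 and 6 days were chosen after the data were examined. Among contigs at 10 FPKM or more, 400 fell and 77 were higher 4-fold or more in both pollination states over the first interval by size alone. The same counts were 708 and 137 over the second interval and 50 and 241 over the third. The 2 states' changes correlated across contigs at 0.743, 0.777 and 0.619.

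**Figure D2:**
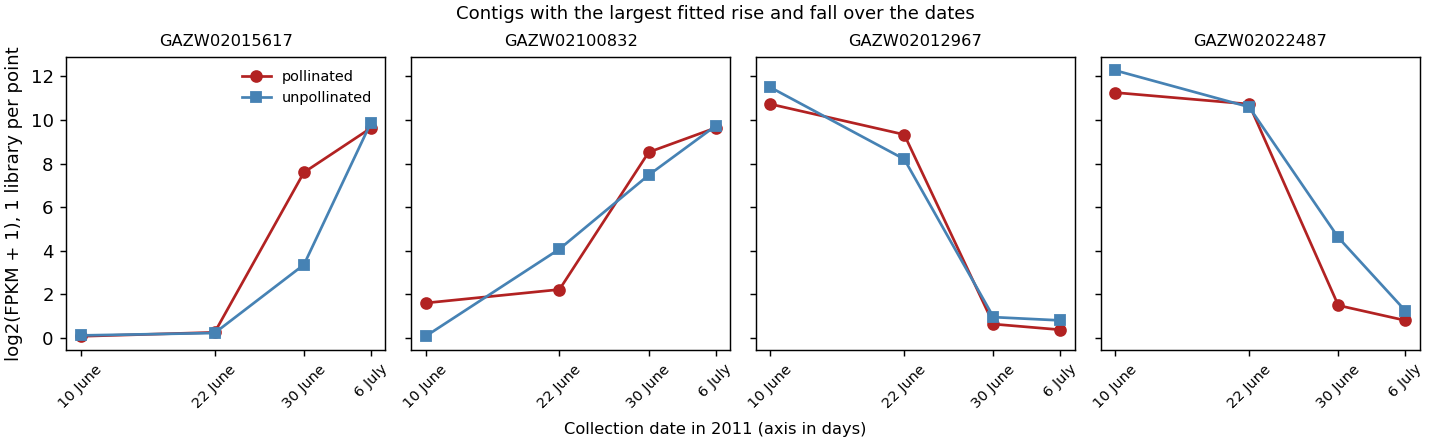
Level of 4 contigs, as log2(FPKM + 1), by collection date in pollinated and unpollinated megagametophytes, 1 library per point. On 6 July GAZW02012967 and GAZW02022487 stood at 1.36 FPKM or less, and GAZW02015617 and GAZW02100832 at 791.4 FPKM or more.

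Pollinated and unpollinated megagametophytes were compared to ask what the presence of pollen and of a growing embryo changes. A single contig, GAZW02094053, passed the test over the 4 dates. It stood at 20.4 to 55.1 FPKM in the 4 pollinated libraries and at 0.0425 to 1.36 FPKM in the 4 unpollinated ones, a limma difference of 4.77 ± 0.21 (SE) log2 units with adjusted p 0.0210, higher on 4 of 4 dates. Its level was 22.1 FPKM in scales and 0.613 FPKM in bracts. The contig with the preceding number was lower in the pollinated library on 4 of 4 dates, but hardly so on 30 June (82.3 against 85.8 FPKM). The sum of both differed by 0.07 log2 units on average over the dates. Only 3 contigs were 2-fold or more higher in the pollinated library on every date and 4 in the unpollinated library.

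The test compared 27065 contigs with date as a block, and 1302 had an unadjusted p under 0.05, where 1353 were expected by chance. The unadjusted count rested on single dates, at 2331 to 2389 without libraries of 22 June and 808 to 823 without libraries of 6 July. In data simulated from these libraries, with few contigs changed, the same test recovered 24% of contigs changed 2-fold and 62% of those changed 4-fold on every date. The call of GAZW02094053 ended without any 1 of the 8 libraries (limma adjusted p 0.169 to 0.541), while its difference stayed at 4.63 to 4.91 log2 units in these fits with fewer residual degrees of freedom. The difference depended on the pseudocount, at 2.98 log2 units with 5 FPKM and 6.63 with 0.1 FPKM, and the call ended with both (limma adjusted p 0.147 and 0.703), the highest p of all alternatives being 0.703 and the lowest 0.0179.

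A difference that grows with date was sought because fertilization and embryo growth occur only after pollination. No contig passed: limma gave 0 of 27065, with 569 at an unadjusted p under 0.05, where 1353 were expected by chance, and a smallest adjusted p of 1. The model had no block for date, so changes shared by both states entered its error. With date as a block, a fit chosen after the data were examined, limma also gave 0, with 1618 at an unadjusted p under 0.05 and a smallest adjusted p of 0.689. A planned contrast of 30 June and 6 July with 10 and 22 June gave 0 in limma too, with 2194 at an unadjusted p under 0.05. In both fits 1353 were expected by chance, so the count lay under or over that value by the form of the model. The contigs with the smallest p in each direction are given as values that did not pass. GAZW02097620 differed by 5.87 ± 0.96 (SE) and GAZW02089245 by -6.05 ± 0.97 log2 units over 26 days between the states, both with limma adjusted p of 1. GAZW02097620 stood at 0.0497 FPKM on 10 June and 4.58 FPKM on 6 July in pollinated megagametophytes, and at 10.2 and 0.0497 FPKM in unpollinated ones. In simulated data with few contigs changed, the test recovered 0% of contigs whose course differed 8-fold and 6% of those that differed 32-fold. With the block it recovered 0% at either size. The count of 0 therefore leaves large differences in few contigs open. Changes in many contigs at once were not simulated.

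At single dates the 2 states were set side by side without a test. Contigs 2-fold or more apart, with the higher value at 10 FPKM or more, numbered 643 on 10 June, 645 on 22 June, 937 on 30 June and 822 on 6 July. Pollinated megagametophytes were higher for 385, 488, 459 and 430 of these, and unpollinated ones for 258, 157, 478 and 392. The widest gaps on the pollinated side were on 30 June, where GAZW02094698 stood at 94.7 against 0.0425 FPKM and GAZW02053960 at 169.1 against 0.919 FPKM. By 6 July these contigs stood at 432.5 and 429.5 FPKM in pollinated and at 327.6 and 57.9 FPKM in unpollinated megagametophytes. On the unpollinated side GAZW02071698 stood at 85.8 against 0.149 FPKM on 6 July and GAZW02059139 at 60.0 against 0.0497 FPKM on 30 June. These differences have no replicate check and compare libraries. Which state had more contigs turned with the rule: at a minimum of 1 FPKM the counts higher in pollinated and in unpollinated megagametophytes were 2143 and 2609 on 10 June, 2382 and 1710 on 30 June and 1973 and 2107 on 6 July, and at 4-fold 84 and 111 on 6 July.

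**Figure D3:**
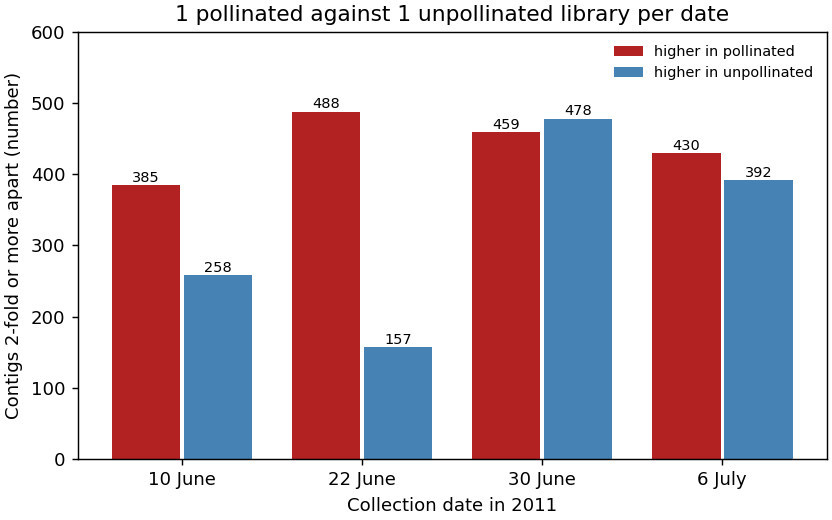
Number of contigs 2-fold or more apart between the pollinated and unpollinated library of each date, with the higher value at 10 FPKM or more, 1 library per state. On 22 June 488 contigs were higher in the pollinated and 157 in the unpollinated library.

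Megagametophytes were compared with scales and bracts to contrast gametophyte with sporophyte tissue. GAZW02021521 stood at 536.5 to 915.5 FPKM in all 8 megagametophyte libraries and at 5.19 FPKM in scales and 1.69 FPKM in bracts. GAZW02013550 stood at 136.2 to 2646 FPKM in megagametophytes and at 1.71 and 2.23 FPKM in scales and bracts. In the other direction, GAZW02041636 reached 387.0 FPKM in scales and 1964 FPKM in bracts and GAZW02041626 483.4 and 775.0 FPKM, and both stayed under 1 FPKM in every megagametophyte library. In limma, 8022 of 29445 contigs differed, 3244 higher and 4778 lower in megagametophytes. This balance turned with the filter, to 2655 higher and 2152 lower at a mean of 5 FPKM or more.

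The differences of GAZW02021521 and GAZW02013550 were 7.47 ± 0.30 (SE) and 7.48 ± 1.18 log2 units, with limma adjusted p of 1.41e-07 and 0.000908. Those of GAZW02041636 and GAZW02041626 were -9.62 ± 0.46 and -8.97 ± 0.30, with limma adjusted p of 3.09e-07 and 1.09e-07. The test treats the 8 megagametophyte libraries as independent, although the 2 of a date are alike, so these p-values are too small by an unknown amount. In the same model the 2 libraries of 10 June against all others gave 3594 contigs. By level alone, 85 contigs were at 10 FPKM or more in all 8 megagametophyte libraries and under 1 FPKM in both sporophyte libraries, and 307 showed the reverse. The first rule asks for 10 FPKM in 8 libraries and the reverse in only 2, so these counts are not like for like. At 1 FPKM or more in any library of a tissue group and under 1 FPKM in all of the other, the counts were 11966 for megagametophytes and 15327 for scales and bracts. Of the latter, 10270 reached 1 FPKM in bracts alone. Contigs at 1 FPKM or more in all 10 libraries numbered 13718. Tissue and collection date could not be separated, and the count was 4765 without scales, 3033 without bracts and 14362 (7063 higher, 7299 lower) with the libraries of 10 June as the only megagametophytes. Without a filter on low values it was 16670 (3420 higher, 13250 lower).

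Similarity of the megagametophyte to sporophyte tissue was higher on each later date in both pollination states. The correlation across contigs with scales went from a mean of 0.562 on 10 June to 0.750 on 6 July, and that with bracts from 0.467 to 0.659. The libraries of a date are not independent of each other, so the 4 dates were permuted: the two-sided exact permutation p was 0.0833 for each tissue, the smallest that 4 dates can give, and 0.0833 after Benjamini-Hochberg adjustment over the 2 tissues, so no p under 0.05 was possible. Sequencing lanes of the libraries are not given in the sources used here.

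**Figure D4:**
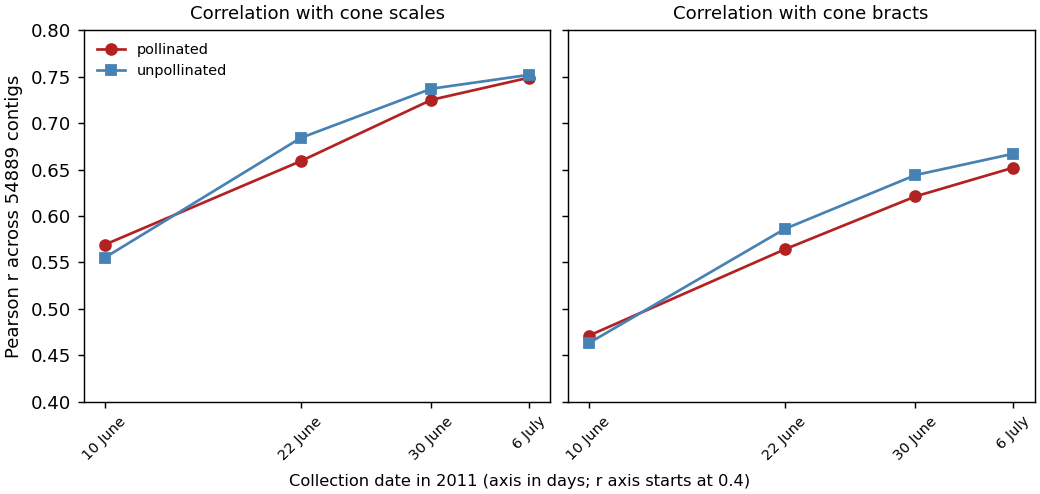
Pearson correlation across contigs of each megagametophyte library with cone scales and with cone bracts, by collection date, 1 point per library. The r axis starts at 0.4. Means went from 0.562 to 0.750 for scales and from 0.467 to 0.659 for bracts.

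Scales and bracts were compared as 1 library each, without a test. Of 10151 contigs at 10 FPKM or more in either, 996 were 2-fold or more higher in scales and 1266 in bracts. GAZW02035022 stood at 896.6 FPKM in scales and 1.5 FPKM in bracts, and GAZW02037646 at 412.0 and 0.659 FPKM. GAZW02021537 stood at 450.9 FPKM in bracts and 1.33 FPKM in scales, and GAZW02036591 at 56.3 and 0.0425 FPKM.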

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

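The tests of alignment with the course over dates, the sign of its rising and falling contigs, the exchange of labels, the summed contig and the carry-over of sporophyte tissue were chosen only after the result was seen. The carry-over test was also restated after its first value was seen. The regroupings of libraries, the share of cases with an opposite neighbour and the share of the rise left without absent contigs were fixed before their results, although examples of opposite neighbours had been seen by then.

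Across 13832 contigs, pollinated minus unpollinated on 22 June correlated at r = -0.485 with the change from 10 to 30 June in the other libraries, the opposite sense to 30 June, where r was 0.40 with the change from 22 June to 6 July. With other contigs, ranks, rescaling or the axis of 1 state alone, the values were -0.488 to -0.364 on 22 June and 0.269 (ranks) to 0.451 on 30 June. On 10 June r was 0.025 with the change from 22 June to 6 July, which leaves out the change from 10 to 22 June. On 6 July r was 0.036 with the change from 22 to 30 June, and 0.12 and -0.087 with the axis of pollinated and of unpollinated libraries alone. These low values do not show that the pools of 10 June were at the same point. The pollinated library of 10 June correlated more highly than the unpollinated one with every later library (0.911 against 0.888 for pollinated 22 June). Each date has a single pair of libraries, and the difference between the dates was not tested. A candidate explanation is that the pools of a date were at different points of 1 shared course, unpollinated further along on 22 June and pollinated on 30 June, but the r of 0.40 raised this explanation and cannot also support it, while a difference in overall scale, which shifts all contigs one way, was argued against by medians of 0.52 for 647 rising contigs and -0.51 for 1070 falling ones. With the labels of 22 June exchanged, 17 contigs were 2-fold or more apart the same way on every date against 7 as labelled. Exchanging 30 June and 6 July together gave 14, and the 7 other arrangements in all gave 3 to 17. The pattern itself moves this count, so an exchange cannot be told apart from the labels. An effect of pollination on the pace of development stays open and untested, as does chance variation between pools.

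A minority of the largest differences at single dates, and the only contig called for pollination, came with an opposite difference in a contig of neighbouring number. Of 949 cases 4-fold or more apart, 16.5% had a neighbour 2-fold or more apart the opposite way, against a median of 4.0% and a highest value of 6.53% over 1000 shifted numberings. A neighbour was in the table for 86.9% of cases, against a median of 74.1% over shifted numberings. Among cases with a neighbour the share was 19.0%, against a highest value of 8.66%. GAZW02094053 summed with the preceding contig, the neighbour chosen for its lower correlation over the libraries, differed by 0.07 log2 units (SD 0.18 over 4 dates), where alone it differed by 4.77 and summed with the following contig by 4.41. Reads moved between related contigs, or a switch between transcript forms of 1 gene, may account for this part. Neighbours also moved the same way in 19.7% of cases against 3.90% over shifted numberings, so nearness of number alone does not give the direction.

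The similarity to scales and bracts was higher on later dates, a trend that 4 dates are too few to test. Without the 11966 contigs under 1 FPKM in both scales and bracts, 57.3% of the increase with scales was left. Those contigs were picked without regard to their course over the dates, so leaving them out does not isolate their loss. Among the 4003 contigs at 10 FPKM or more in all 10 libraries, the increase was 0.230 with scales and 0.248 with bracts. Over all contigs it was 0.188 and 0.192. The increase thus depends on the contigs compared, so the share left does not measure what the absent contigs contribute. Whether loss of contigs absent from scales and bracts accounts for the trend stays open. Scale or bract tissue at 1% or more of the 6 July dissections could not be ruled in or out, since the profile of that tissue on 6 July was not measured. Of 31 contigs abundant in sporophyte tissue on 26 May and absent on 10 June, 61.3% stayed under 1% of their sporophyte level on 6 July (median 0.471%, quartiles 0.228% and 4.11%). A biological convergence of expression stays open as a hypothesis, and so does the dependence on tissue collected only on 26 May.

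Other splits of the libraries were counted for each limma test. For pollination, 4 of the 32 splits of the 8 libraries that could be fitted gave 1 contig or more, with at most 3 in another split. Only 8 splits part the libraries of all 4 dates, as the real one does. Of these, 2 gave 1 contig or more, the real one included, so chance was not excluded. For the interaction, 8 of 8 exchanges within dates gave 0 contigs, and 8 are too few for a share under 0.05. For tissue, 1 of 45 choices of 2 libraries gave as many as 8022, the highest other being 3594 for the 2 libraries of 10 June. Choices across dates gave 4 or fewer and are no fair comparison for scales and bracts, which share a date, and the 5 pairs that share a date are too few for a share under 0.05, so chance was not excluded. For date, 1 of 12 orders of the 4 dates gave as many as 8853, the highest other being 6577, and 12 are too few for a share under 0.05.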

How the results depend on the processing

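The intervals between dates, the date means, the interaction with a date block, the summed contigs, the tissue test without 10 June and the similarity restricted to a mean of 1 FPKM or more were alternatives chosen only after the result was seen. The contigs named for date, pollination over all dates and tissue kept their direction under the alternatives that fitted each on its own. Summed with the preceding contig, GAZW02094053 differed by 0.07 log2 units, from -0.143 to 0.255 over the dates. The other named contigs were not rerun. Libraries were nearest to the other library of their date in 8 of 8 cases under both alternatives tried.

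The date count of 8853 stayed within 1.5 times under 21 of 32 alternatives, but its balance of 4402 up and 4451 down became 5313 and 4400 under quantile normalization, 5579 and 4412 at a common sum, 3399 and 2632 at a mean of 5 FPKM and 3387 and 4834 without a filter. It was 4453 at adjusted p under 0.01, 2423 on date means (fewer residual degrees of freedom), 2652 to 9408 over fits leaving out 1 library or 1 date, 0 in the 4 pollinated and 1827 in the 4 unpollinated libraries alone (fewer libraries), and 5147, 2415 and 472 for the single intervals. The pollination count of 1 was 0 in limma with a pseudocount of 0.1 or 5 FPKM, without a filter, at adjusted p under 0.01, without the date block, in the 3 dates after 10 June, with neighbouring contigs summed in 1 of the pairings, and in every fit leaving out libraries or dates (0 to 0), with 281 to 2389 contigs at an unadjusted p under 0.05. The interaction count was 0 under all 25 alternatives. Contigs at an unadjusted p under 0.05 numbered 203 (of 13832 tested) to 2565 (of 54889). With 30 June and 6 July against 10 and 22 June they numbered 2194 of 27065, where 1353 were expected by chance. The tissue count of 8022 was 16670 without a filter (more contigs tested), 4807 at a mean of 5 FPKM (fewer), where 2655 higher and 2152 lower turned the balance, 4619 at adjusted p under 0.01, 3033 to 4765 without scales or bracts, and 14362 with 10 June alone. Without 10 June it was 9369. The lone library left in such fits was assumed to vary like the megagametophytes. Except where fewer or more contigs or libraries entered, the cause was not tested.

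Pairs of a date numbered 230, 232, 292 and 195 contigs at 4-fold, and 4752, 3331, 4092 and 4080 with the minimum at 1 FPKM. The state with more contigs turned on 10 June (2143 higher in pollinated, 2609 in unpollinated), 30 June (2382 and 1710) and 6 July (1973 and 2107) at 1 FPKM, and on 6 July (84 and 111) at 4-fold. Scales and bracts differed 4-fold for 782. No paired analysis was possible because each group has 1 library, as far as pairing by replicate number goes. Pairing by date was part of the pollination test. The set tests of the gene lists and their alternatives were not run, since the table pairs no names with the contigs. Depth is unknown, so its effect on low contigs could not be measured.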

Other observations

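The sets and the peak dates described in this part were chosen after the result was seen, and no explanation was tested for them. Most contigs that varied over the dates were highest on the first or the last. Among 13541 contigs at 10 FPKM or more in any megagametophyte library, 4300 varied 4-fold or more over the dates on the mean of both states. Of these, 2128 peaked on 10 June, 352 on 22 June, 420 on 30 June and 1400 on 6 July. The same peak date held in pollinated and unpollinated megagametophytes for 3656 contigs, or 85.0%. Choosing contigs on the mean of both states favours those that moved alike in both, so this share is raised by an unknown amount.

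The bracts held 10270 contigs at 1 FPKM or more that were under 1 FPKM in the other 9 libraries, against 1305 in scales. Their median level in bracts was 1.46 FPKM, and 74.2% were under 2 FPKM. Contigs abundant on 10 June and under 2 FPKM on 6 July and in scales were seen at low level in bracts, at a median of 0.703% of their 10 June level for contigs at 20 to 100 FPKM, 0.241% at 100 to 500 FPKM and 0.141% at 500 FPKM or more. For the last of these the medians were 1.11 FPKM in bracts, 0.505 in scales and 0.261 and 0.553 on 6 July, where scales and 6 July were held under 2 FPKM by the choice of contigs and bracts were not.

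A search for contigs present only with pollen late in development found few. Contigs at 5 FPKM or more in pollinated megagametophytes on 30 June and 6 July, under 1 FPKM in them on 10 June and under 1 FPKM in every unpollinated library numbered 2, and 3 showed the reverse. Exchanging the states within dates gave totals of 3 to 5 in the 7 other arrangements, against 5 as labelled.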
